A study of Saccharomyces cerevisiae with 12 samples.

How the data were processed

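Expression was measured by RNA sequencing in 12 libraries of BY4741 yeast, 3 each of a wild type and of swp82, snf2 and snf5 deletion strains. Per the labels, cultures were grown at 30 °C to log phase (OD600 of 0.75 to 1.0) as independent biological replicates, total RNA was extracted with hot acid phenol, and stranded mRNA libraries were made. Groups and replicate numbers were taken from the sample labels.

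The submitters' processing notes name TopHat2 2.0.10, Bowtie2 2.1.0, edgeR 3.8.6 and the build sacCer3. The counting tool, its strand setting, its treatment of reads that fit several places, the annotation and the filter on genes are not given in the sources used here. The deposited table holds 12 columns of a normalised signal, CPM divided by a TMM factor. That is how the values behave: the authors' signal is in whole multiples of the value of 1 read for 100% of values in each library (largest deviation 5.53e-05 of a read, tolerance 0.05). The reads were recovered from these steps, and TMM factors computed from them differed from those in the deposited values by at most 1.48e-11. The signal is called scaled CPM here. A second deposited table holds group means of the same signal for a filtered list of genes, with no per-library values. By the name of the deposited list, its filter was a fold change of 2 and a p-value of 0.05. Which comparisons it was applied to, and whether the p was adjusted, are not given in the sources used here, and the list was compared with the calls only by membership and by ratios of the authors' means.

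Recovered depth was 9012746 to 12875057 reads per library, scaling factors were 0.907 to 1.08, and 1 read was worth 0.0801 to 0.118 scaled CPM. The 10 genes with the most reads held 7.53 to 11.2% of a library. Replicates of a group differed by more than sampling noise (chi-square per degree of freedom of 3.01 to 80.9; correlation of log2 values across genes 0.978 to 0.998), so no library was taken as a copy of another. Intervals and floors cover counting error only.

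The test planned before the data were examined was edgeR's quasi-likelihood test on counts, with limma on log2 values as the stated alternative for normalised values. Because the deposited unit is a normalised signal, limma was the main test. limma 3.58.1 (R 4.3.3, trend option) was fitted to log2(value + 1) over all 12 libraries with group as the only term, for genes with a value of at least 1 in at least 3 libraries. This left 5820 genes and removed 115. A gene was called at a two-sided Benjamini-Hochberg adjusted p under 0.05. Fold changes on this scale understate the change of low genes. edgeR 4.0.16 was run on the recovered reads as an alternative chosen after seeing the data, and called 1716 genes in the snf5, 1653 in the snf2 and 198 in the swp82 deletion against the wild type, and 729 between the snf5 and snf2 deletions. DESeq2 1.42.0 and edgeR's exact test were run on the same reads.

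Gene lists were written before the data were examined. Of 40 lists, those of the deleted genes and of the marker genes were not tested as lists, and the other 38 were tested with camera at a preset correlation of 0.01, in the comparisons of each deletion with the wild type and of the snf5 with the snf2 deletion, 152 tests adjusted together. The result of 1 list and of 1 named gene is not reported here. None of the calls held with an estimated correlation, where the lowest adjusted p was 0.0965. The median of no called list changed sign under another scaling.

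Named genes followed a rule fixed before the data were examined. It takes the deleted genes and all SWI/SNF subunit genes, and in each comparison up to 10 genes with the highest and 10 with the lowest fold change among those called, changed at least 2-fold, with a mean of at least 10 reads per library in the higher group and no overlap between replicates. It also takes from each list up to 4 called members with the smallest p, or the member with the smallest p where none was called. Marker genes are given apart: LEU2 is given as a result, HIS3 was measured, and URA3 and MET17 were not analysed here. A few genes outside the rule are named in the closing section, where they are said to have been chosen after their values were seen.

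Coordinates and neighbours come from assembly R64, of which sacCer3 is the UCSC copy; 5685 identifiers matched it and 250 did not. Reads are uncertain for genes with near-identical copies (HXT, COS, PAU and THI families, PHO11 with PHO12, ADH1 with ADH2, CSS1 with its relatives, enolase and TDH paralogs, and many ribosomal protein pairs). They are also uncertain for genes that overlap another, such as SER3 with SRG1, PHO84 with the non-coding RNA YNCM0001W and YDR210W-B with YDR210W-A.

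Whether replicate numbers pair the libraries was checked from deviations from the group means. All 3 same-numbered pairs correlated above 0.1 in the comparison of the swp82 deletion with the wild type (0.255 to 0.599) and with the snf5 deletion (0.116 to 0.660). In the other 4 comparisons not all 3 did. Replicate 1 paired in every comparison, with correlations of 0.401 to 0.660 and the same number the best match both ways. Between the swp82 deletion and the wild type the same number was the best match both ways for replicates 1 and 2. It was not for replicate 3. Between the swp82 and snf5 deletions it was so only for replicate 1. The pairing comes from the data, since the labels give no shared day or batch. The blocked fit is given beside the counts, gene lists and genes described in the comparison of the swp82 deletion with the wild type where it changed their call or moved their count by over 1.5 times. Not every list or gene whose call it changed is described.

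The procedure was tested on simulated reads with known changes. For the snf5 deletion comparison 91.8% of 2-fold, 70% of 1.5-fold and 8% of 1.25-fold changes were called, with 5.67% of calls false. For the snf2 deletion these were 91.8%, 76%, 20.4% and 4.70%, and for the swp82 deletion 93.9%, 82%, 14% and 4.70%, so most changes of 1.25-fold in single genes were missed. The list test called 10 of 10 shifted lists and 1 of 370 unshifted ones. These were random lists of genes simulated independently of each other. The rate of false list calls therefore does not cover lists whose members vary together.

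Settings chosen in advance were other scalings of the recovered reads, other pseudocounts and filters, the other tests, only the compared groups in the fit, a replicate block, other thresholds, other list tests and leaving out each library. Scalings planned for edgeR were applied to the limma test, and the planned prior count of 5 became a pseudocount of 5. Added after seeing the data were edgeR's quasi-likelihood test, a covariate for the axis of variation within groups, a fit without replicate 1 of every group, and the replicate block for the calls shared between deletions.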

Results

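RNA was measured in 12 libraries of budding yeast, Saccharomyces cerevisiae strain BY4741, in 4 groups of 3: a wild type and strains lacking SNF5, SNF2 or SWP82. These genes encode subunits of SWI/SNF, a complex that uses ATP to remodel nucleosomes; Snf2 is its ATPase. The series asked what loss of Snf5 does to the complex, its expression profile included. The libraries held 9012746 to 12875057 reads assigned to genes, and 5820 genes passed the filter and were tested. Values are scaled CPM, given as mean ± SD with n = 3 libraries per group unless stated otherwise, and log2 fold changes are given ± SE on the log2(value + 1) scale. Per the labels the wild type carries a FLAG tag with LEU2 on Snf2, and the deletion strains carry it on Snf6. By these labels tag position goes with every comparison against the wild type. LEU2 had reads in the wild type and the snf5 deletion and none in the snf2 and swp82 deletions, so LEU2 status goes with the comparisons of either of the latter with the wild type or the snf5 deletion.

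The deleted genes were nearly without reads in their own strains. SNF5 (YBR289W, chromosome II, 779667 to 782384 in R64) stood at 99.4 ± 2.46 in the wild type and 0.0611 ± 0.106 in the snf5 deletion. The 2 reads there were 0.0623% of the wild-type level (95% exact interval of counting error, 0.00755 to 0.225%). SNF2 (YOR290C, chromosome XV, 855147 to 860258) fell from 97.6 ± 5.21 to 0.649 ± 0.136 in the snf2 deletion, and its 22 reads were 0.658% of the wild-type level (0.412 to 0.997%). SWP82 (YFL049W, chromosome VI, 36803 to 38674) had 0 reads in the swp82 deletion against 59.8 ± 0.287 in the wild type, at least 545-fold lower by a floor of 3 reads over the group. LEU2 (YCL018W, chromosome III, 91324 to 92418), which encodes isopropylmalate dehydrogenase of leucine synthesis, also had 0 reads in every swp82 and snf2 deletion library, at least 512-fold and 641-fold below the wild type's 56.2 ± 0.869. In the snf5 deletion LEU2 stood at 74.7 ± 16.1, or 133% of the wild type (125 to 141%). Its call as higher there (0.38 ± 0.13, limma adjusted p = 0.0481) was lost without any 1 of wild-type replicates 1 to 3 or snf5 deletion replicates 1 or 3, with an adjusted p of up to 0.144, and its fold change was 0.25 without replicate 3 of the snf5 deletion. DESeq2 (adjusted p = 0.0598), edgeR's quasi-likelihood test (0.0870) and a pseudocount of 0.1 (0.109) did not call LEU2 there. The labels give the LEU2-linked tag for all 4 strains, so LEU2 in the swp82 and snf2 deletion libraries goes against that label. HIS3, the other marker gene measured, had a fold change of 0.24 (adjusted p = 0.169) in the snf5 deletion and -0.43 (adjusted p = 0.0746, or 0.0490 with the replicate block) in the swp82 deletion.

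**Figure D1:**
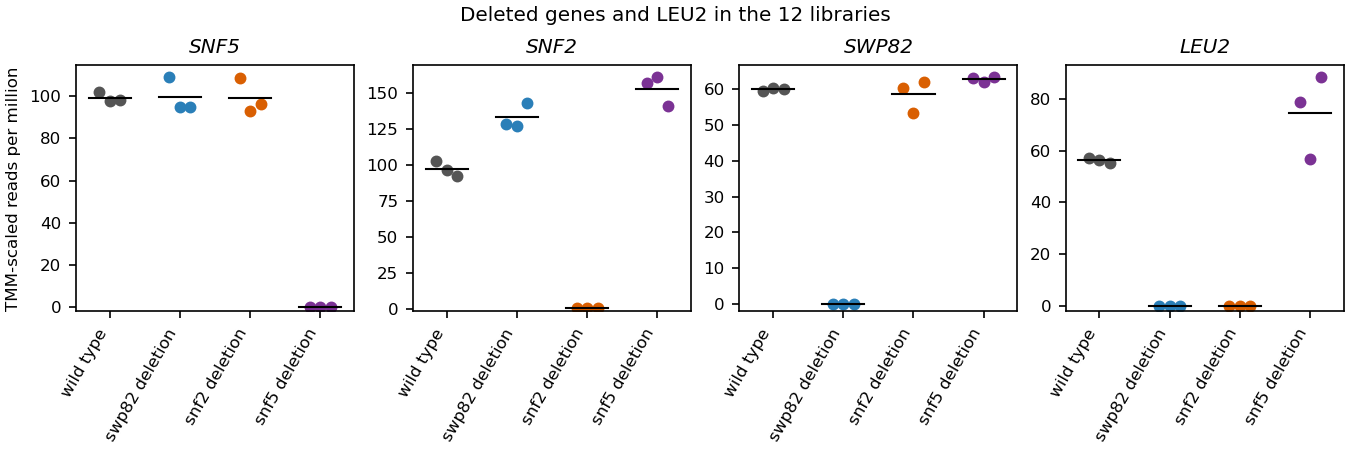
Scaled CPM (y axis, linear) of SNF5, SNF2, SWP82 and LEU2 in each of the 12 libraries; points are libraries and horizontal lines are group means. Each deleted gene is near 0 in its own strain, and LEU2 is at 0 in the swp82 and snf2 deletions.

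Among the other subunit genes, SNF2 was higher in the snf5 deletion (153 ± 10.8; 0.64 ± 0.08, limma adjusted p = 0.000166) and in the swp82 deletion (133 ± 8.85; 0.44 ± 0.08, adjusted p = 0.0163) than in the wild type, where the gene carries the tag. The call in the swp82 deletion was lost without wild-type replicate 2 or 3 or swp82 deletion replicate 3, with an adjusted p of up to 0.0696. In the snf5 deletion 4 of 11 other subunit genes were called higher and 0 lower (4 and 0 adjusted over the list alone). TAF14 was higher by 0.20 ± 0.04. RTT102 and ARP7, which encode small and actin-related subunits, were each higher by 0.17 ± 0.05, but these 2 calls were lost without any of several libraries. RTT102 lost its call without wild-type replicates 1 or 3 or snf5 deletion replicates 2 or 3 (adjusted p up to 0.152), and ARP7 without any wild-type replicate or snf5 deletion replicates 1 or 2 (up to 0.0806). In the snf2 deletion limma called 0 of 11 (0 adjusted over the list alone), with 2 at an unadjusted p under 0.05, while edgeR's quasi-likelihood test and DESeq2 each called 1. SNF6 had the smallest p there (0.22 ± 0.08, adjusted p = 0.0521). In the swp82 deletion SNF2 was the 1 subunit gene called (2 higher and 1 lower adjusted over the list alone), and ARP9 joined it with the replicate block (0.18, adjusted p = 0.0377).

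Loss of Snf5 was compared with the wild type to describe the expression profile without this subunit. PHO84 (YML123C, chromosome XIII, 24037 to 25800), the high-affinity phosphate transporter, fell from 95.7 ± 14.1 to 0.711 ± 0.229 (log2 fold change -5.82 ± 0.18, limma adjusted p = 2.76e-09). QDR2, a multidrug transporter, and HO, the mating-type switching endonuclease, also fell (-5.38 ± 0.11 and -4.44 ± 0.13). SED1, an abundant cell wall protein, went from 5790 ± 502 to 294 ± 63.9 (-4.32 ± 0.19). In the other direction MET3 (YJR010W, chromosome X, 456239 to 457774), which encodes ATP sulfurylase of sulfate assimilation, rose from 57.8 ± 1.68 to 596 ± 91.1 (3.33 ± 0.09, adjusted p = 7.53e-10). STR3 had the largest fitted rise among the named genes (3.41 ± 0.48), with a wide spread in the deletion (54.6 ± 43.5 against 3.21 ± 0.829). The remaining genes with the lowest fold changes were ZEO1 (-4.54), HSP12 (-4.44), YRO2 (-4.37), YHB1 (-4.27), YGR035C and TIR1 (both -3.97). Those with the highest were MET2 (2.90), CLD1 (2.72), SUL2 (2.65), YMR244W (2.61), MET6 (2.55), RCK1 (2.50), STE3 (2.44) and MET28 (2.42).

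Sulfur and methionine genes rose together in the snf5 deletion. Of 25 members, 22 were called higher and 1 lower (22 and 1 adjusted over the list alone), with a median log2 fold change of 1.32. They included SUL2, a sulfate permease (2.65 ± 0.14), and MET10, a sulfite reductase subunit (1.78 ± 0.11). The list was called by camera (adjusted p = 8.21e-13), and the call was lost with an estimated correlation (adjusted p = 0.404 with an estimated correlation). Mating and pheromone genes of MATa cells fell, with 20 of 26 called lower and 1 higher (21 and 2 adjusted over the list alone; median -0.71). Examples were SST2, a regulator of G-protein signalling (-1.39 ± 0.07), FAR1, which arrests the cycle during mating (-1.03 ± 0.06), and the agglutinin subunit AGA2 (-1.50 ± 0.11). The camera adjusted p was 1.57e-10, and the adjusted p = 0.36 with an estimated correlation. Pleiotropic drug response genes were called lower in 9 of 10 cases (0 higher and 9 lower adjusted over the list alone; median -0.87), among them the transporters TPO1 (-2.46 ± 0.10) and YOR1 (-1.01 ± 0.07). Camera called that list at adjusted p = 2.23e-07, with an adjusted p = 0.0965 with an estimated correlation, the lowest such value of any list and comparison, shared with 1 list in the snf2 deletion.

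Genes of carbon metabolism moved both ways. Of 17 glycolysis and fermentation genes, 13 were called lower and 2 higher (13 and 2 adjusted over the list alone; median -0.29). The pyruvate kinase gene CDC19 went from 13046 ± 117 to 6502 ± 636 (-1.01 ± 0.09) and enolase ENO2 fell by 0.90 ± 0.07, while the hexokinase gene HXK2 rose by 0.78 ± 0.08 (camera adjusted p = 0.000806; adjusted p = 0.44 with an estimated correlation). Of 20 genes of gluconeogenesis, the glyoxylate cycle and acetate use, 10 were called higher and 0 lower (10 and 0 adjusted over the list alone; median 0.43), including the transcription factors ADR1 (0.84 ± 0.13) and CAT8 (0.94 ± 0.16). Camera gave an adjusted p = 7.30e-05 and an adjusted p = 0.154 with an estimated correlation. Of 23 iron regulon genes, 13 fell and 4 rose (13 and 5 adjusted over the list alone), from the siderophore transporters SIT1 (-2.51 ± 0.17) and ARN1 (-1.86 ± 0.09) to the reductase gene FRE4, which rose by 2.38 ± 0.11 (camera adjusted p = 0.0119; adjusted p = 0.44 with an estimated correlation). Cell wall genes fell in 16 of 32 cases and rose in 4 (18 and 5 adjusted over the list alone), with the glucanase EXG1 at -1.43 ± 0.07 and TIR3 at -2.34 ± 0.14 (camera adjusted p = 0.000444; adjusted p = 0.337 with an estimated correlation). Of 16 genes of the phosphate regulon, 9 fell and 2 rose (9 and 3 adjusted over the list alone), with VTC3 at -0.49 ± 0.06 and PHO81 at -0.47 ± 0.07 beside PHO84 (camera adjusted p = 0.0423; adjusted p = 0.404 with an estimated correlation).

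In all, limma called 1704 genes in the snf5 deletion, 862 higher and 842 lower, of which 111 and 162 changed at least 2-fold. With total-count scaling the split was 1368 higher and 549 lower. That scaling moved the median of all genes to 0.08.

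Loss of the ATPase Snf2 gave a profile led by many of the same transcripts. SER3 (YER081W, chromosome V, 322686 to 324095), phosphoglycerate dehydrogenase of serine synthesis, rose from 79.2 ± 5.44 to 1232 ± 45.5 in the snf2 deletion (3.94 ± 0.08, limma adjusted p = 6.15e-11). It overlaps the transcript SRG1 in the annotation, so its reads are uncertain. FMP48 rose by 3.35 ± 0.31, MET2 by 3.12 ± 0.19 and PDC6, a minor pyruvate decarboxylase, by 2.99 ± 0.22. PHO84 fell to 0.553 ± 0.172 (-5.96 ± 0.18, adjusted p = 2.14e-09), QDR2 by 4.69 ± 0.11 and HO by 4.12 ± 0.13. Further named genes were MET3 (3.08), SUL2 (2.97), CLD1 (2.85), ADH2 (2.79), CSS1 (2.75) and RCK1 (2.65) among those higher. Among those lower were TIR1 (-3.91), YHB1 (-3.86), YGR035C (-3.69), AZR1 (-3.48), ZEO1 (-3.36), MRH1 (-3.30) and CAR2 (-3.22).

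Cytosolic ribosomal protein genes fell together in the snf2 deletion: 122 of 137 were called lower and 2 higher (132 and 2 adjusted over the list alone), by a median of -0.33. RPL8A fell by 0.69 ± 0.07 and RPL4A by 0.42 ± 0.05 on the log2 scale. Camera gave an adjusted p = 1.47e-27 and an adjusted p = 0.44 with an estimated correlation. With total-count scaling the median of all genes rose to 0.13 and that of this list to -0.19, so the list stayed lower. Of 33 respiratory chain and ATP synthase genes, 18 were called higher and 0 lower (24 and 1 adjusted over the list alone; median 0.39), such as ATP3 (0.52 ± 0.07) and COX5A (0.55 ± 0.08), at a camera adjusted p = 3.01e-07 and an adjusted p = 0.52 with an estimated correlation. Gluconeogenesis, glyoxylate and acetate genes rose in 12 of 20 cases, with 0 lower (16 and 0 adjusted over the list alone; median 0.59), including ADR1 (1.16 ± 0.13) and the isocitrate lyase gene ICL1 (0.52 ± 0.08). For that list camera gave an adjusted p = 2.71e-07 and an adjusted p = 0.0965 with an estimated correlation. Histone genes rose in 6 of 10 cases with 0 lower (6 and 0 adjusted over the list alone; median 0.41): the histone H4 gene HHF1 rose by 0.74 ± 0.06 and the histone H3 gene HHT1 by 0.60 ± 0.07 (camera adjusted p = 0.000702; adjusted p = 0.404 with an estimated correlation).

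Sulfur genes were again higher in the snf2 deletion, 19 of 25, with 2 lower (20 and 3 adjusted over the list alone; median 1.21; camera adjusted p = 5.35e-10; adjusted p = 0.422 with an estimated correlation). MATa mating genes were lower in 15 of 26 cases and higher in 1 (15 and 2 adjusted over the list alone), with FAR1 at -1.09 ± 0.06 (camera adjusted p = 5.48e-06; adjusted p = 0.422 with an estimated correlation). Drug response genes were lower in 8 of 10 cases and higher in 1 (8 and 1 adjusted over the list alone), with the transporter gene PDR5 at -1.98 ± 0.18 (camera adjusted p = 1.50e-05; adjusted p = 0.123 with an estimated correlation). Serine and one-carbon genes parted: SER3 rose while the glycine cleavage genes GCV1 (-2.26 ± 0.10), GCV2 (-1.44 ± 0.11) and GCV3 (-1.47 ± 0.08) fell, making 6 of 11 lower and 2 higher (6 and 2 adjusted over the list alone). That list was called at a camera adjusted p = 0.0472, with an adjusted p = 0.721 with an estimated correlation.

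For the snf2 deletion limma called 1612 genes, 792 higher and 820 lower, of which 121 and 122 changed at least 2-fold. The split was 1000 higher and 689 lower with upper-quartile factors, and 1838 and 468 with total-count scaling.

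The swp82 deletion differed from the wild type at fewer called genes. LEU1 (YGL009C, chromosome VII, 476313 to 478652), isopropylmalate isomerase of leucine synthesis, rose from 178 ± 4.27 to 677 ± 85 (1.92 ± 0.19, limma adjusted p = 0.000381). The branched-chain aminotransferase gene BAT1 rose by 1.27 ± 0.16 and OAC1, a mitochondrial carrier, by 1.37 ± 0.19. PHO84 fell to 7.07 ± 2.12 (-3.60 ± 0.18, adjusted p = 1.41e-06) and DDR2, a stress-response gene, by 3.12 ± 0.38. ARG1, argininosuccinate synthetase, fell from 85.7 ± 11.7 to 19.9 ± 3.3 (-2.06 ± 0.30). Other named genes that kept their calls without any 1 library of the 2 groups were ANB1 (1.08), ALR2 (1.07), YRO2 (-2.05) and YDR210W-B (-1.58), the last of which overlaps YDR210W-A. Another 8 of the 18 genes with the largest changes did not keep theirs: FIG1 (1.29), YIR042C (1.13), ROF1 (1.05), GPH1 (-2.61), HSP12 (-2.32), HSP26 (-2.14), GAD1 (-1.72) and FRE7 (-1.56). Each of the 6 libraries ended the call of at least 1 of them when left out, with adjusted p of up to 0.178.

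Stress genes were lower and ribosome genes higher in the swp82 deletion as lists, and the number of their members called singly depended on the replicate block. Of 31 genes of the Msn2 and Msn4 stress response and of trehalose and glycogen metabolism, 2 were called lower, DDR2 and GPH1, and 0 higher, or 21 and 0 with the replicate block (19 and 0 adjusted over the list alone, without the block; median -0.86; camera adjusted p = 1.33e-09; adjusted p = 0.493 with an estimated correlation). Ribosome biogenesis genes had a median of 0.37 with 0 of 68 called by limma (0 adjusted over the list alone), 3 at an unadjusted p under 0.05 and 0 called by edgeR's quasi-likelihood test or DESeq2, and NOP16 had the smallest p (0.51 ± 0.18, adjusted p = 0.129, or 0.0230 with the replicate block, which called 7 of the list higher and 0 lower). Camera called that list higher (adjusted p = 8.46e-08; adjusted p = 0.721 with an estimated correlation). Ribosomal protein genes had 9 of 137 called higher and 0 lower, or 99 and 0 with the block (123 and 0 adjusted over the list alone; median 0.23; camera adjusted p = 1.87e-31; adjusted p = 0.422 with an estimated correlation). RPS8A (0.32 ± 0.06) was one of them, and its call was lost without wild-type replicates 1 or 2 or swp82 deletion replicates 2 or 3 (adjusted p up to 0.0749). Phosphate genes were lower in 4 of 16 cases and higher in 0 (8 and 0 adjusted over the list alone), with VTC3 at -0.53 ± 0.06 (camera adjusted p = 2.29e-05; adjusted p = 0.123 with an estimated correlation). MATa mating genes went up in this strain, where 3 of 26 were called higher and 0 lower, or 10 and 0 with the block (10 and 0 adjusted over the list alone; median 0.28; camera adjusted p = 5.24e-08; adjusted p = 0.404 with an estimated correlation). Glycine cleavage genes fell here too: GCV1 by 1.15 ± 0.10, GCV2 by 1.27 ± 0.11 and GCV3 by 0.61 ± 0.08. The serine and one-carbon list that holds them was not called by camera here (median -0.11). With the block, 4 of its 11 members were called lower and 0 higher.

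Libraries stood apart along the same lists. Relative to the wild-type mean, the stress list averaged 0.36, -0.18 and -0.18 on the log2 scale in wild-type replicates 1 to 3 and -0.52, -1.29 and -1.27 in the swp82 deletion. It averaged 0.27, -0.58 and -1.27 in the snf5 deletion and 0.43, 0.03 and 0.22 in the snf2 deletion. Within each group ribosome biogenesis was highest where the stress list was lowest. It was -0.22 in wild-type replicate 1 and 0.57 in swp82 deletion replicate 2, and lay between -0.76 and 0.24 in the snf5 deletion. The main axis of variation within groups held 61.1% of the variance within groups. Replicate 1 lay lowest on it in every group. Its deviation from the group mean was -6.90 in the wild type and -11.7, -3.87 and -17.6 in the swp82, snf2 and snf5 deletions. Whether replicates of the same number shared a batch is not given in the labels.

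**Figure D2:**
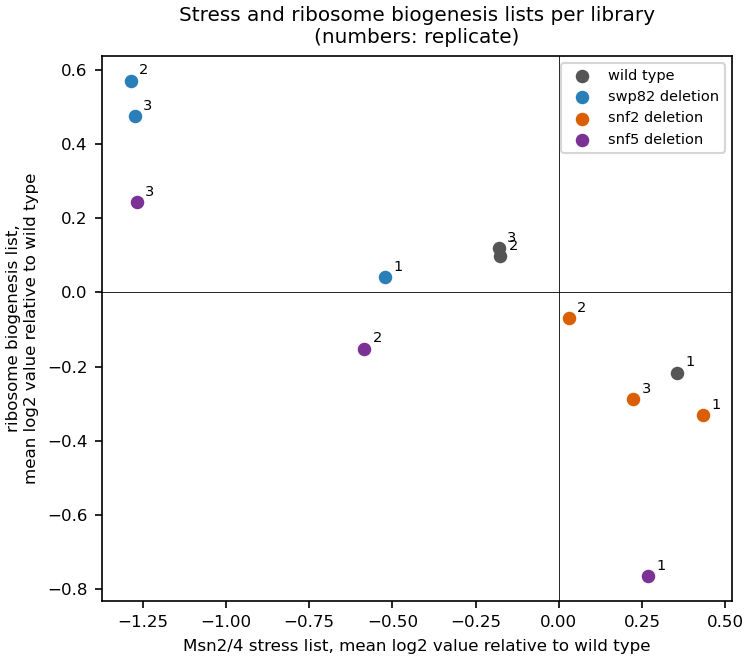
Mean log2 value relative to the wild-type mean of the Msn2/4 stress list (x axis) and of the ribosome biogenesis list (y axis) in each of the 12 libraries, with the replicate number beside each point. Within each group the library with the lowest stress value has the highest ribosome biogenesis value. The same holds over all 12 libraries for swp82 deletion replicate 2 (-1.29 and 0.57). Libraries of different groups do not all follow this order: snf5 deletion replicate 2 has -0.58 and -0.15, and wild-type replicate 3 has -0.18 and 0.12. The 3 snf5 deletion libraries spread from 0.27 to -1.27 on the x axis.

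For the swp82 deletion limma called 203 genes, 82 higher and 121 lower, of which 8 and 26 changed at least 2-fold. With the replicate number as a block, 783 genes were called, 394 higher and 389 lower, among them all 203, and 57 changed at least 2-fold. The block also brought the chaperone list past the threshold (camera adjusted p = 0.0491 in place of 0.126; adjusted p = 0.852 with an estimated correlation, without the block), with 1 higher and 3 lower of 24 called with the block and 0 higher and 2 lower without it. Leaving out wild-type replicate 1, 2 or 3 left 63, 65 or 75 calls, leaving out swp82 deletion replicate 2 or 3 left 79 or 95, and leaving out swp82 deletion replicate 1 gave 625. The count without replicate 1 of every group was 496. The split was 50 higher and 273 lower with total-count scaling, and 266 and 223 with DESeq2.

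The snf5 and snf2 deletions were compared directly to ask where loss of Snf5 differs from loss of the ATPase. LEU2 had reads in the snf5 deletion and 0 in the snf2 deletion, so LEU2 goes with this comparison. SER3 stood at 139 ± 14.5 in the snf5 deletion and 1232 ± 45.5 in the snf2 deletion (-3.15 ± 0.08, limma adjusted p = 3.58e-10). HSP12, a small heat shock protein, was at 2.11 ± 0.786 and 163 ± 10.7 (-5.76 ± 0.52, adjusted p = 0.000124), and the secreted glycoprotein gene YGP1 was lower by 3.16 ± 0.31. The arginine synthesis genes ARG1 (YOL058W, chromosome XV, 219211 to 220473; 2.60 ± 0.30) and ARG3 (2.11 ± 0.35) and asparagine synthetase ASN1 (1.30 ± 0.20) were higher in the snf5 deletion, where ARG1 ranged widely (365 ± 195 against 55.5 ± 12.3). Other named genes were IMD2 (1.21), PCL5 (1.19), DIP5 (1.17) and YMR206W (1.02) on the higher side and FMP48 (-2.76), SED1 (-2.36), HSP26 (-2.31), ARO9 (-2.20) and DDR2 (-2.18) on the lower. XBP1 (-2.12) lost its call without snf2 deletion replicates 1 or 3 or snf5 deletion replicate 2 (adjusted p up to 0.063), and RTC3 (-2.13) without any snf2 deletion replicate or snf5 deletion replicates 2 or 3 (up to 0.152). DESeq2 (0.0614) and edgeR's quasi-likelihood test (0.0627) did not call RTC3.

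Amino acid genes of the Gcn4 response were higher in the snf5 than in the snf2 deletion in 23 of 42 cases and lower in 1 (29 and 2 adjusted over the list alone; median 0.37), with ARO1 of aromatic amino acid synthesis at 0.82 ± 0.07 and ASN2 at 0.47 ± 0.06. Camera called the list (adjusted p = 1.86e-12; adjusted p = 0.47 with an estimated correlation). Ribosomal protein genes were higher in 56 of 137 cases and lower in 0 (99 and 0 adjusted over the list alone; median 0.22; camera adjusted p = 2.59e-28; adjusted p = 0.44 with an estimated correlation). Respiratory genes were lower in 15 of 33 cases and higher in 0 (26 and 0 adjusted over the list alone; median -0.38), with the NADH dehydrogenase gene NDE1 at -0.95 ± 0.09 and QCR6 at -0.72 ± 0.10 (camera adjusted p = 8.21e-13; adjusted p = 0.422 with an estimated correlation). Stress genes were lower in 7 of 31 cases and higher in 0 (10 and 0 adjusted over the list alone; median -0.47), with catalase CTT1 at -1.65 ± 0.22 (camera adjusted p = 2.45e-05; adjusted p = 0.721 with an estimated correlation). In that list the snf5 deletion libraries spanned 0.27 to -1.27. Histone genes were lower in 5 of 10 cases and higher in 1 (8 and 2 adjusted over the list alone), with HHF1 at -0.83 ± 0.06 (camera adjusted p = 0.000286; adjusted p = 0.404 with an estimated correlation). MATa mating genes were lower in 9 of 26 cases and higher in 0 (14 and 0 adjusted over the list alone), with STE6, the a-factor exporter, at -0.25 ± 0.05 (camera adjusted p = 9.57e-05; adjusted p = 0.474 with an estimated correlation). Ergosterol genes were higher in 8 of 25 cases and lower in 0 (12 and 0 adjusted over the list alone), with ERG12 at 0.48 ± 0.05 (camera adjusted p = 1.76e-05; adjusted p = 0.36 with an estimated correlation).

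Between these deletions limma called 726 genes, 337 higher and 389 lower in the snf5 deletion, of which 10 and 45 differed at least 2-fold. Without snf2 deletion replicate 1, 2 or 3 the count was 322, 349 or 375, and without snf5 deletion replicate 2 it was 482. The count at least 2-fold was 83 without snf5 deletion replicate 1. With total-count scaling the split was 246 higher and 545 lower. Among subunit genes TAF14 was called higher (0.17 ± 0.04) and SNF6 lower (-0.26 ± 0.08). Both calls were lost without any 1 snf2 deletion replicate or snf5 deletion replicate 2, TAF14 also without snf5 deletion replicate 1 and SNF6 also without replicate 3 (adjusted p up to 0.104 and 0.154). TAF14 was also not called with total-count scaling (0.134), nor SNF6 with RLE scaling (0.0526) or edgeR's quasi-likelihood test (0.0505). Per the labels SNF6 carries the tag with LEU2 in both strains. With 0 LEU2 reads in the snf2 deletion, tag status at SNF6 may differ between them, which was not tested.

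The fold changes of the snf5 and snf2 deletions against the wild type were close across genes. Of 5815 genes, leaving out the deleted and marker genes, 974 were called in the same direction in both, 468 of them lower, and 7 in opposite directions. Lists drawn independently would share 235, and unchanged groups simulated with a shared control group shared 0. The simulated genes were unchanged and varied independently, so almost none could be called and a count near 0 was fixed in advance. The simulated values show only what a shared control gives without any change. The correlation across genes, which are not independent replicates, was 0.830 (Pearson; Spearman's rho 0.718) against a simulated Pearson value of 0.494, and the covariance was 0.193 against a simulated 0.00881. Part of the excess of shared calls over independent lists may come from the shared controls, which could not be split into groups of at least 2. The simulated covariance already holds the shared control, and the measured one lay 0.184 above it. Of the 974 genes, 127 also differed directly between the deletions, and 11 of these at least 2-fold. Of 720 genes called in the snf5 deletion and not in the snf2 deletion, 266 differed directly, as did 220 of the 629 with the reverse pattern.

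**Figure D3:**
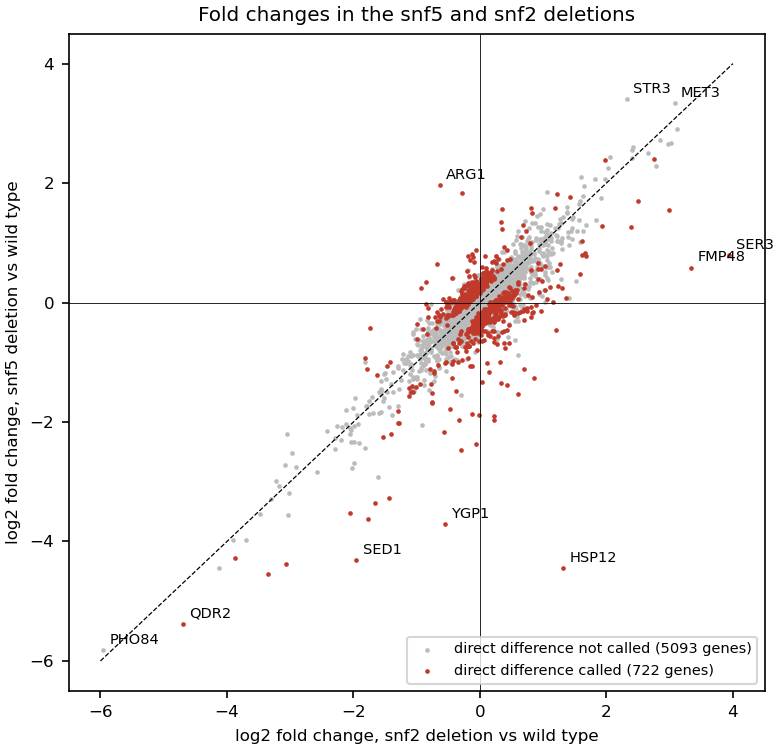
Log2 fold change against the wild type in the snf2 deletion (x axis) and the snf5 deletion (y axis), 1 point per tested gene, with the deleted and marker genes left out; red points differed in the direct comparison and the dashed line marks equal fold changes. PHO84 lies near the line at -5.96 and -5.82, while SER3 (3.94 in the snf2 deletion) and HSP12 (-4.44 in the snf5 deletion) lie off it.

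The calls of the swp82 deletion were set against those of the other deletions in the fit without the replicate block. With the snf5 deletion, 91 genes were called in the same direction and 29 in the opposite one (29.2 by independent lists, 0 simulated; Pearson correlation across genes 0.174 against a simulated 0.498; Spearman's rho -0.0172; covariance 0.0239 against 0.00886). With the snf2 deletion, 83 were called in the same direction and 35 in the opposite one (27.8 by independent lists, 0.01 simulated; Pearson correlation 0.0205 against 0.498; Spearman's rho -0.153; covariance 0.00268 against 0.00889). Part of the excess of shared calls may come from the shared controls. Without wild-type replicate 1, 2 or 3 the shared calls fell to 35 to 39 and to 33 to 38. With the block, 213 genes were called in the same direction and 137 in the opposite one with the snf5 deletion (136 by independent lists), and 175 and 260 with the snf2 deletion (131 by independent lists). With the snf2 deletion the opposite calls were thus the more numerous. All values by independent lists are for the same direction, and none was computed for the opposite one. The block also entered the fits of the snf5 and snf2 deletions against the wild type, where replicate numbers did not pair all the libraries. The simulations were not run with the block, and their shared counts near 0 were again fixed in advance.

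The remaining comparisons set the swp82 deletion, which had 0 LEU2 reads, against the snf5 deletion, which had LEU2 reads, and the snf2 deletion, which had 0. Against it, the snf5 deletion had ARG1 higher by 4.02 ± 0.30 (365 ± 195 against 19.9 ± 3.3), the cardiolipin deacylase gene CLD1 by 3.54 ± 0.14 and MET3 by 3.25 ± 0.09. QDR2 was lower (-5.30 ± 0.11), as were YGR035C (-4.86 ± 0.15; 6.87 ± 1.88 against 225 ± 28) and GPX2, a peroxidase gene (-4.05 ± 0.12). Limma called 2438 genes there, 1189 higher and 1249 lower, and ARP7 (0.18 ± 0.05) was the 1 subunit gene of 10 called (1 adjusted over the list alone). In the snf2 deletion SER3 was higher than in the swp82 deletion by 3.79 ± 0.08, CLD1 by 3.67 ± 0.14 and HSP12 by 3.63 ± 0.52, and QDR2 was lower by 4.61 ± 0.11. There limma called 2533 genes, 1265 higher and 1268 lower, with SWI3 (0.20 ± 0.05) and SNF6 (0.31 ± 0.08) higher among 10 subunit genes and ARP9 lower (-0.17 ± 0.06, adjusted p = 0.0380), or 2 higher and 0 lower adjusted over the list alone. ARP9 lost its call without swp82 deletion replicates 2 or 3 or any snf2 deletion replicate (adjusted p up to 0.132), and stood at 0.0477 with total-count scaling, which moved all genes. With the axis of variation within groups as a covariate, SNF6 (0.18, adjusted p = 0.0831) and ARP9 (-0.06, adjusted p = 0.411) were not called. Total-count scaling moved the median of all genes to 0.16 in the first of these comparisons and 0.21 in the other. The splits became 2283 higher and 601 lower, and 2939 and 577, while upper-quartile factors gave 1612 and 1015 in the other.

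**Figure D4:**
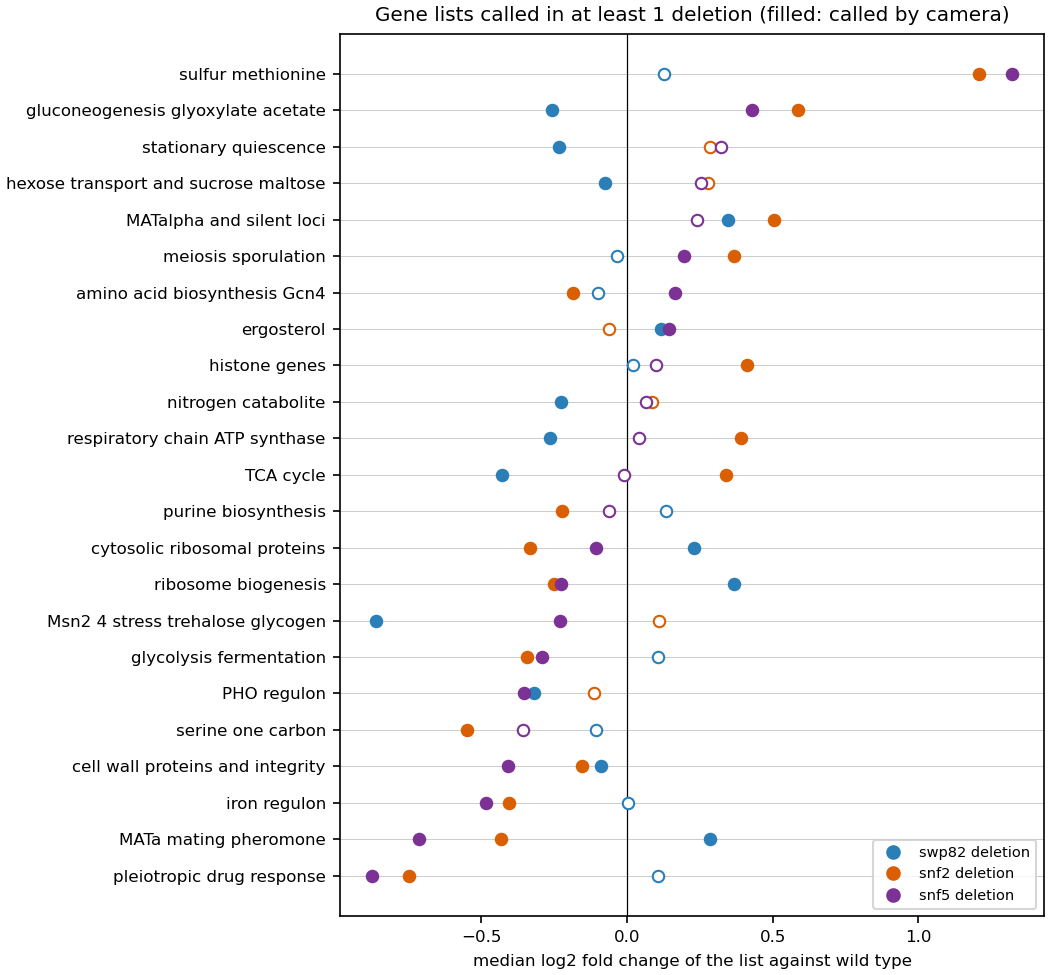
Median log2 fold change against the wild type (x axis) of the plotted gene lists, each called in at least 1 deletion (y axis), 1 point per deletion; filled points were called by camera with its preset correlation. Sulfur and methionine genes have medians of 1.32 and 1.21 in the snf5 and snf2 deletions, and the stress list has -0.86 in the swp82 deletion.

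The authors deposited a filtered list of genes with group means. On that list, 501 genes had at least a 2-fold ratio of means in some deletion against the wild type, 368 in the snf5, 359 in the snf2 and 105 in the swp82 deletion. Of the listed genes, 463 were tested here, 43 were below the filter on low values, and 422 were called in some deletion against the wild type. Of 347 genes called here with at least a 2-fold change, 335 were on the list and 12 were not. The list was chosen on these same libraries and is no independent evidence of its direction.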

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

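Both tests of Leu3-regulated genes were chosen only after the result was seen, as were the axis score as a covariate and both tests of the stress and chaperone genes in the snf5 against the snf2 deletion, whose gene set was widened to all list members. The genes ICS2, YBL029C-A, YER188C-A, GTT2, OMS1, MNN4 and GGC1, and those of the Leu3 list, were chosen after their values were seen.

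Some genes were called in opposite directions in different deletions, and the deletions also differed directly at them. In the snf5 and snf2 deletions there were 7: ICS2 (difference -1.14, from -0.68 and 0.46), YBL029C-A (-0.89, from -0.47 and 0.42), YER188C-A (-0.85, from -0.50 and 0.36), GTT2 (-0.84, from -0.47 and 0.37), OMS1 (-0.48, from -0.22 and 0.26), MNN4 (-0.46, from -0.25 and 0.21) and GGC1 (0.85, from 0.40 and -0.44). There were 29 such genes in the snf5 and swp82 deletions. Among them were YGR035C (difference -4.86, from -3.97 ± 0.15 and 0.88 ± 0.15), CLD1 (3.54, from 2.72 and -0.82) and ARG1 (4.02, from 1.96 ± 0.30 and -2.06 ± 0.30). In the snf2 and swp82 deletions there were 35, including YGR035C (difference -4.58, from -3.69 and 0.88), ANB1 (-1.66, from -0.58 and 1.08) and CLD1 (3.67, from 2.85 and -0.82).

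Some Leu3-regulated genes were higher than in the wild type in the strains without LEU2 reads. In the swp82 deletion LEU1 (1.92), OAC1 (1.37), BAT1 (1.27) and GDH1 (0.67) of 7 genes were called higher, in the snf2 deletion the same 4 (1.66, 1.06, 0.77 and 1.12), and in the snf5 deletion, which has LEU2 reads, LEU1 (0.83) and GDH1 (1.17). The list was put together after its members' values were seen, so no list test is given; its medians were 0.67, 0.77 and 0.22 in the swp82, snf2 and snf5 deletions, with LEU4 at -0.18 and ILV5 at -0.11 in the snf2 deletion. Mislabelled deletion libraries are argued against, since the deleted gene stood at no more than 0.760% of its wild-type mean in any library of its strain. Lack of LEU2 may contribute and stays open. Against the snf5 deletion the median was 0.0873 in the snf2 deletion (quartiles -0.19 to 0.68) and 0.276 in the swp82 deletion (-0.10 to 1.06). LEU1 and OAC1 were called lower in the snf5 than in the snf2 deletion (-0.83 and -1.01), and LEU4 higher (0.51). In the snf5 against the swp82 deletion LEU1 (-1.08), BAT1 (-1.04) and OAC1 (-1.32) were called lower, and LEU4 (0.43) and GDH1 (0.50) higher.

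The stress list was lower and the ribosome biogenesis list higher in the swp82 deletion than in the wild type by camera, with 2 of 31 and 0 of 68 genes called by limma (21 and 7 with the replicate block; for the 68, 3 at an unadjusted p under 0.05 and 0 by edgeR's quasi-likelihood test or DESeq2) and both list calls lost with an estimated correlation (adjusted p = 0.493 and 0.721 with an estimated correlation). Lack of LEU2 is argued against as the whole cause, since the stress list had a median of 0.11 in the snf2 deletion, which also lacks LEU2 reads, unless loss of Snf2 opposes it, which was not tested. The position of the libraries on the axis of variation within groups could account for part of the pattern and stays open. With the axis score as a covariate, 47.1% of the stress median was kept, from -0.86 to -0.41. The ribosome biogenesis median went from 0.37 to 0.00. Quartiles over the stress genes went from -1.44 and -0.51 to -0.62 and -0.15, the latter 72.2 and 17.7% of the median without the covariate. These quartiles give the spread between genes and not the uncertainty of the share kept. Calls in the stress list went from 2 to 17 under that covariate. Loss of Swp82 is the biological explanation the design gives and was not told apart from it.

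Stress and chaperone genes were lower in the snf5 than in the snf2 deletion, with a median of -0.39 over the 55 members of both lists and 10 called lower. By camera, 0 list calls in this comparison held with an estimated correlation, and the 55 genes were not tested as a set. Lack of LEU2 in the snf2 deletion is argued against as the whole cause, since these genes had a median of -0.61 in the swp82 deletion against the wild type (quartiles -1.16 to -0.20), where LEU2 is also missing, unless loss of Swp82 opposes it, which was not tested. The position of the libraries on the axis of variation within groups could account for part of the pattern and stays open. With the axis score as a covariate, 40.7% of the median was kept, from -0.39 to -0.16. Quartiles over these genes went from -0.82 and -0.14 to -0.43 and 0.09, the latter 110 and -22.4% of the median without the covariate. They too give the spread between genes and not the uncertainty of the share kept. Calls among these genes went from 10 to 20 under that covariate. A difference between loss of Snf5 and loss of Snf2 is the biological explanation the design gives and was not told apart from it.

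The 6 libraries of each comparison make 10 splits, too few for a share under 0.05. In each of the 6 comparisons only the real split, 1 of 10, reached its own count. The real counts were 1704 (snf5 deletion against wild type), 1612 (snf2), 203 (swp82), 726 (snf5 against snf2), 2438 (snf5 against swp82) and 2533 (snf2 against swp82). The highest count of another split was 0 in 5 comparisons and 749 in that of the snf5 with the swp82 deletion, for the split that set swp82 deletion replicate 1 and snf5 deletion replicates 1 and 2 against the rest. That split parts 1 same-numbered pair, and the other splits that part all 3 pairs called 0.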

How the results depend on the processing

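The axis score covariate, the fit without replicate 1 of every group, edgeR's quasi-likelihood test and the replicate block for shared calls were chosen only after the result was seen. The cause of the differences given here was not tested, except that an adjusted p under 0.01 lowers counts by construction. Of 8400 alternatives run for 560 named-gene results, 7871 kept direction and side of the threshold, 444 lost the call, 82 gained one and 3 reversed. A filter on mean log-CPM was not run. Depth limits genes of few reads, since 1 read was worth up to 0.118 scaled CPM.

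For the snf5 deletion against the wild type (1704 genes called), the count was 2723 with the axis score, 984 at adjusted p under 0.01 and 276 at unadjusted p under 0.05 with a 2-fold change. Of the 1704 genes, 273 changed at least 2-fold, and 178 genes were called with such a change with a pseudocount of 5. For the snf2 deletion against the wild type (1612), it was 2475 with only the 2 groups in the fit, 972 at adjusted p under 0.01 and 248 at unadjusted p under 0.05 with a 2-fold change, and 2-fold changes went from 243 to 159 with a pseudocount of 5. For the swp82 deletion against the wild type (203), it was 323 with total-count scaling, 489 with DESeq2, 328 with edgeR's exact test, 131 with only the 2 groups, 783 with the replicate block, 457 with the axis score, 496 without replicate 1 of every group, 60 at adjusted p under 0.01 and 57 at unadjusted p under 0.05 with a 2-fold change. Leaving out 1 library gave 63 (wild-type replicate 1) to 625 (swp82 deletion replicate 1). Its 34 genes with a 2-fold change became 63 with DESeq2, 65 with the exact test, 57 with the block, 70 without replicate 1 of every group and 26 to 67 leaving out 1 library.

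For the snf5 against the snf2 deletion (726), the count was 225 with only the 2 groups, 1692 with the axis score, 241 at adjusted p under 0.01, 62 at unadjusted p under 0.05 with a 2-fold change and 322 (snf2 deletion replicate 1) to 908 (snf5 deletion replicate 1) leaving out 1 library. Its 55 genes with a 2-fold change became 35 with a pseudocount of 5 and 43 to 83 leaving out 1 library. For the snf5 against the swp82 deletion (2438), it was 1314 with only the 2 groups, 1441 at adjusted p under 0.01 and 309 at unadjusted p under 0.05 with a 2-fold change, and 2-fold changes went from 299 to 191 with a pseudocount of 5. For the snf2 against the swp82 deletion (2533), it was 1519 at adjusted p under 0.01 and 348 at unadjusted p under 0.05 with a 2-fold change, and 2-fold changes went from 343 to 209 with a pseudocount of 5.

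With total-count scaling TAF14 (0.15), RTT102 (0.22) and ARP9 (0.0477) changed sign in the snf2 against the swp82 deletion, as that scaling moved the median of all genes there to 0.21, about as far as these genes. Subunit genes called with that scaling were 6 in the snf2 and 2 in the swp82 deletion against the wild type, 1 in the snf5 against the snf2 deletion, 7 in the snf5 against the swp82 deletion and 6 in the snf2 against the swp82 deletion. DESeq2 called 1 subunit gene in the snf2 deletion against the wild type and 2 in the snf5 against the swp82 deletion. RLE scaling left 1 in the snf5 against the snf2 deletion, and the replicate block gave 2 in the swp82 deletion against the wild type. Leaving out 1 library gave 2 to 4 subunit genes in the snf5 deletion and 0 to 3 in the swp82 deletion against the wild type, 0 to 2 in the snf5 against the snf2 deletion and 1 to 2 in the snf5 against the swp82 deletion.

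Camera with an estimated correlation called 0 lists in the snf5 deletion against the wild type, 0 in the snf2 deletion against the wild type, 0 in the swp82 deletion against the wild type and 0 in the snf5 against the snf2 deletion, while fry called 19, 21, 12 and 13. The correlation of the snf2 and swp82 deletions' fold changes was 0.0205, or -0.00863 with a pseudocount of 5, 0.00417 with a filter of at least 10 scaled CPM in 3 samples, and 0.0283, 0.0462 and 0.0472 without wild-type replicates 1, 2 and 3. Without 1 wild-type replicate, calls shared by the snf5 and swp82 deletions were 35 to 39 in place of 91, and those shared by the snf2 and swp82 deletions 33 to 38 in place of 83. With the replicate block they were 213 and 175. In the swp82 deletion against the wild type the block also ended the call of the MATalpha list (camera adjusted p = 0.0412 to 0.0582), moved respiratory genes called lower from 1 to 18 and those of the TCA cycle from 1 to 9, and called TDH1 (-1.35, adjusted p = 0.0121), COS12 (-1.31, 0.0331), STE3 (0.62, 0.0270), OPI3 (-0.33, 0.0364) and HHO1 (-0.18, 0.0364).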

Other observations

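The genes beside the deletions and at chromosome ends named here were chosen after their values were seen, and no test was added for them beyond the list of genes near chromosome ends.

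Other gene groups moved without being described above. Ergosterol synthesis genes were higher in the snf5 deletion in 11 of 25 cases and lower in 2 (11 and 3 adjusted over the list alone), with ERG2 at 0.70 and HMG1 at -0.86 (camera adjusted p = 0.0192; adjusted p = 0.49 with an estimated correlation). In the snf2 deletion iron regulon genes were lower in 14 of 23 cases and higher in 4 (14 and 5 adjusted over the list alone; camera adjusted p = 0.00775; adjusted p = 0.44 with an estimated correlation). MATalpha-specific genes, normally silent in MATa cells, were higher there in 3 of 5 cases and lower in 0 (3 and 0 adjusted over the list alone), with the a-factor receptor gene STE3 at 2.05 (camera adjusted p = 0.0295; adjusted p = 0.36 with an estimated correlation). In the swp82 deletion cell wall genes were lower in 6 of 32 cases and higher in 1 (7 and 1 adjusted over the list alone), with CWP2 at -0.57 (camera adjusted p = 0.0179; adjusted p = 0.404 with an estimated correlation), and the glucose-signalling gene MTH1 was at -0.96. Of the lists tested, 26 were called in at least 1 comparison and 12 in none (camera adjusted p of 0.0513 to 0.960).

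A gene beside SNF5, APM3, was higher in the snf5 deletion (0.82 ± 0.08, limma adjusted p = 2.55e-05) and not called in the snf2 (-0.12) or swp82 (0.09) deletion. ALR2, beside SWP82, was higher in the swp82 deletion (1.07 ± 0.07) and not called in the snf5 (-0.07) or snf2 (-0.02) deletion. Genes within 30 kb of a chromosome end, 285 in number, had medians of 0.04, 0.05 and -0.03 in the snf5, snf2 and swp82 deletions and were not called as a list (camera adjusted p = 0.274, 0.272 and 0.0734).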
